A study of Mus musculus with 4 samples.

How the data were processed

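Splenic B cells from mice were cultured for 4 days with anti-CD40 at 1 ng/ml and IL-4 at 20 ng/ml, which drives class switching to IgG1 and IgE, and joins of DNA breaks in the Sμ switch region to other sites were read by linear amplification from a primer in Sμ, a nested PCR and MiSeq sequencing, per the labels' protocols. The enzyme AflII removed unrearranged Sμ sequence, per the labels' protocols. Reads were aligned to mm9 with Bowtie2, per the submitters' processing notes. How junctions were called, filtered and deduplicated is not given in the sources used here. The growth protocol gives a 129Sv background and the strain label gives BL6, so the strain was not settled.

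Each of the 4 libraries is 1 genotype, and there are no replicates. Groups were taken from the sample titles. The deposited summary of each library gives counts of junctions by the place of the prey end (the partner of the Sμ bait) and by the overlap or insertion at the join, in bins set by the authors. These counts were used as deposited. Deposited position lists give 1 mm9 coordinate per junction in Sμ, Sγ1 and Sε, and their lengths equalled the summary counts in every library. The fraction values in the deposited histograms divide each bin by the junctions of that strand, per the file headers and the values themselves, and were not used in any test. Junction tables give the read, the bait and prey alignments and the position of each join. Some of these tables were analysed for only part of the libraries: the table of junctions outside IgH was not used here for CtIP_AA, and that of large insertions was not used here for XRCC4_KO. Emptied lines in the tables (36 of 365 outside IgH and 18 of 710 large insertions in Wildtype, for example) were kept in counts of lines and left out where a position was needed.

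The share of junctions in each class was computed per library with a 95% Wilson interval. Pairs of libraries were compared with the two-sided Fisher's exact test on junction counts and the conditional odds ratio with its exact 95% interval. Such a test compares 2 libraries, not 2 genotypes, and its interval covers counting error only. Benjamini-Hochberg adjustment was made within each kind of result over its pairs and classes, with a threshold of 0.05. The 3 mutant libraries were each compared with Wildtype, and 2 further pairs (CtIP_AA with CtIP_KO, and CtIP_KO with XRCC4_KO) were second-line. Medians of position and of bait length and means of microhomology length were compared with two-sided permutation tests of 100000 resamples, with 95% bootstrap intervals from 10000 resamples. The smallest p such a test can give is 1e-05. Odds ratios stratified by region are Mantel-Haenszel estimates, with an exact p conditional on the totals of each region.

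Microhomology is overlap between bait and prey alignments in the read. Long microhomology was set at 4 or more bp, over joins with 1 to 15 bp. The deposited summary already counts microhomology over 15 bp, which was subtracted for this share. Deletional junctions are those on the minus strand, the orientation that most Sγ1 and Sε junctions of the Wildtype library take. The core of each switch region was set as the central 95% of deletional Wildtype junctions, so the Wildtype share beyond it is fixed by construction. Bait length runs from the nested primer to the bait end, in reads whose bait alignment ended within 10 bp of the most frequent end. Bait mutation rates are mismatched over sequenced bait bases of Sε junctions, from the deposited counts, which do not include insertions or deletions. Bases of 1 read are not independent, so the intervals of these rates are too narrow.

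Sites named outside IgH are, by a rule set before the data were examined, up to 10 bins of 1 Mb per library with 3 or more distinct junctions. A list of genes known as off-target sites of AID, the deaminase that starts switching, was also set, but the gene table at hand is for GRCm38.p6 and not mm9, so no gene was assigned and the list gave no result. The tests were tried on simulated libraries of the real sizes drawn from the Wildtype shares or Sε positions. Junctions were drawn independently and with no variation between libraries of 1 genotype, so these simulations cover counting error only. With no change, none of 100 simulations per library called the Sε share. A true odds ratio of 0.8 was called in 96%, 98% and 99% of simulations at the sizes of CtIP_AA, CtIP_KO and XRCC4_KO. A call there was an adjusted p under 0.05 over the classes of 1 pair, fewer tests than in the real adjustment. A shift of 200 bp in the Sε median was called in 100%, 100% and 94% of 50 simulations, and no shift in 8%, 6% and 8%. These used an unadjusted threshold of 0.05 and fewer resamples than the real tests. Alternatives changed the denominator, the treatment of repeated positions, cut-offs, regions and borders. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.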

Results

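Junctions between DNA breaks in Sμ, the switch region upstream of the IgM constant gene, and other sites in the genome were compared in activated B cells of 4 genotypes, with 1 library each and no replicates. The Wildtype library (CD21Cre, CtIP +/C and XRCC4 +/C in its label) held 9435 junctions. CtIP_AA (homozygous for the CtIP T855A substitution) held 3220. CtIP_KO (CD21Cre, CtIP C/- and XRCC4 +/C) held 2555 and XRCC4_KO (CD21Cre, CtIP +/- and XRCC4 C/-) held 3521. CtIP is a DNA end resection factor, and XRCC4 is the partner of DNA ligase IV in classical end joining. The label of CtIP_AA names no Cre and no XRCC4 allele, so this library differs from Wildtype in more than the substitution. That of XRCC4_KO gives CtIP +/-, and that of Wildtype gives CtIP +/C with Cre, so both may hold 1 working CtIP copy after deletion. The labels of Wildtype and CtIP_KO give XRCC4 +/C with Cre, so both may also hold 1 working XRCC4 copy. Because each genotype is 1 library, every p below compares libraries by their junction counts.

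The first question was where the Sμ breaks were joined. In Wildtype, 42.8% of junctions (95% Wilson interval 41.8 to 43.8) landed in Sγ1, 27.8% (26.9 to 28.7) in Sε, 24.7% (23.8 to 25.6) in Sμ itself, 0.827% elsewhere in IgH and 3.87% (3.50 to 4.28) outside IgH. In XRCC4_KO, junctions to Sε fell to 13.1% (12.0 to 14.3), an odds ratio of 0.392 against Wildtype (95% interval 0.351 to 0.436, Fisher's exact adjusted p = 5.1e-73). Junctions within Sμ rose to 31.9% (odds ratio 1.43, exact adjusted p = 1.13e-15), those outside IgH to 7.84% (odds ratio 2.11, adjusted p = 7.67e-18) and those elsewhere in IgH to 1.96% (odds ratio 2.40, adjusted p = 1.26e-06). The share in Sγ1 was 45.2% (odds ratio 1.10, exact adjusted p = 0.0247), a difference lost when each prey position was counted once (odds ratio 1.05).

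**Figure D1:**
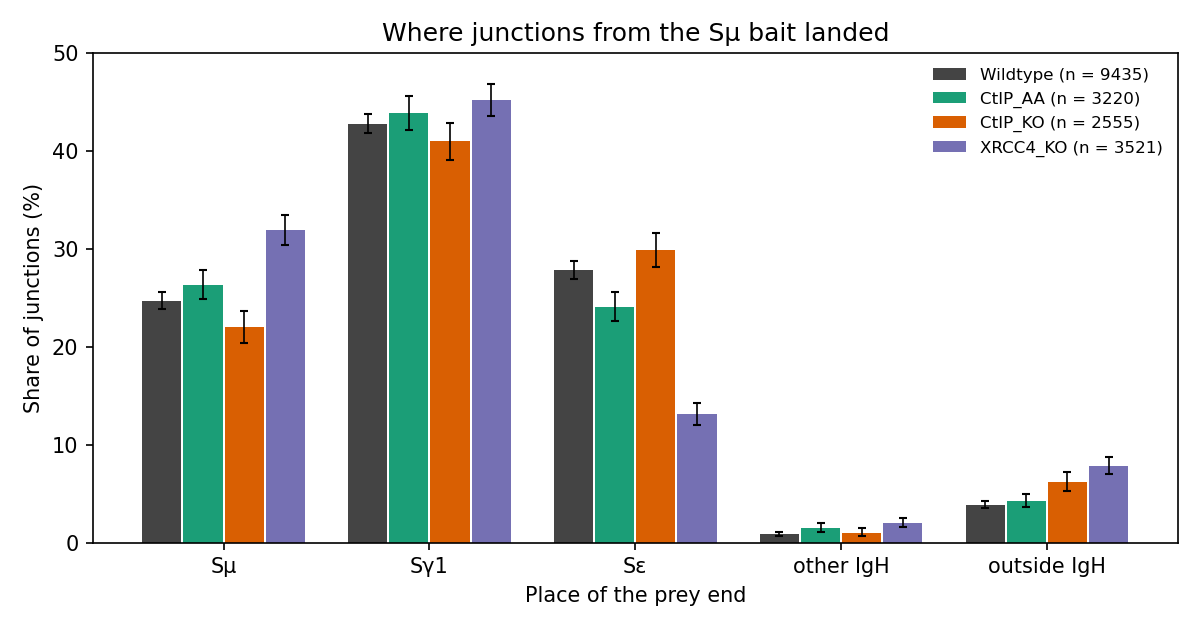
Share of junctions (%) by the place of the prey end for the 4 libraries. Bars are shares of all junctions of a library and error bars are 95% Wilson intervals, which cover counting error only. Sε takes 13.1% of junctions in XRCC4_KO and 24.0 to 29.9% in the other libraries.

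The CtIP libraries differed less from Wildtype. In CtIP_AA, Sε took 24.0% of junctions (22.6 to 25.5), an odds ratio of 0.821 (0.747 to 0.901, exact adjusted p = 6.96e-05), and the rest of IgH took 1.49% (odds ratio 1.81, adjusted p = 0.00363). In CtIP_KO, Sε took 29.9% (odds ratio 1.10, 1.00 to 1.22, exact adjusted p = 0.059), which did not pass the test. It passed with junctions outside IgH left out (odds ratio 1.15, 1.04 to 1.26, exact adjusted p = 0.0101), and not without Sμ (odds ratio 1.06, adjusted p = 0.297) or with each prey position counted once (odds ratio 1.09, adjusted p = 0.151). In the same library Sμ fell to 22.0% (odds ratio 0.861, exact adjusted p = 0.00811) and junctions outside IgH rose to 6.18% (odds ratio 1.64, 1.34 to 1.99, adjusted p = 3.29e-06). Counting each prey position once, with fewer junctions, gave an odds ratio of 0.892 for Sε in CtIP_AA (upper limit 0.992) and of 0.879 for Sμ in CtIP_KO (0.779 to 0.990). Neither passed the test then (exact adjusted p = 0.0577 for each). CtIP_AA and CtIP_KO differed from each other in Sε with an odds ratio of 0.743 (exact adjusted p = 2.66e-06).

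As a measure of switch products, Sε junctions were taken over Sε plus Sγ1. The share was 39.4% in Wildtype (38.2 to 40.6), 35.4% in CtIP_AA (33.4 to 37.4), 42.2% in CtIP_KO (39.9 to 44.4) and 22.5% in XRCC4_KO (20.8 to 24.4). The odds ratio against Wildtype was 0.842 in CtIP_AA (exact adjusted p = 0.00103), 1.12 in CtIP_KO (adjusted p = 0.0349) and 0.447 in XRCC4_KO (adjusted p = 6.39e-46). Counting each prey position once left only the XRCC4_KO difference past the threshold (odds ratio 0.530), with 0.906 for CtIP_AA and 1.11 for CtIP_KO.

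The structure of the joins separated XRCC4_KO from the other libraries. Blunt joins, with neither overlap nor added bases, made up 22.2% of Wildtype junctions (21.4 to 23.1) and 12.6% (11.6 to 13.7) in XRCC4_KO, an odds ratio of 0.504 (exact adjusted p = 7.33e-36). Joins with microhomology rose from 49.9% to 67.2% (odds ratio 2.06, exact adjusted p = 3.98e-69) and joins with insertions fell from 27.9% to 20.2% (odds ratio 0.654, adjusted p = 9.13e-19). In CtIP_KO the blunt share was 23.9% and the microhomology share 50.1%, neither distinguishable from Wildtype (odds ratios 1.10 and 1.01, exact adjusted p = 0.141 and 0.882). Insertions were lower without passing the test (odds ratio 0.909, exact adjusted p = 0.118). The insertions of over 30 bp described below are mostly reads without a read length or with the bait primer as prey. Counting them as insertions lowers the blunt and microhomology shares by itself. With them counted among the joins, the directions turned. The odds ratio became 0.941 for blunt joins (exact adjusted p = 0.363), 0.817 for microhomology (adjusted p = 2.5e-06) and 1.30 for insertions (adjusted p = 6.11e-09). None of these shares passed the test under the other alternatives (exact adjusted p = 0.0774 or more). In CtIP_AA blunt joins were 22.0% (exact adjusted p = 0.882), microhomology 47.3% (odds ratio 0.901, adjusted p = 0.0268) and insertions 30.7% (odds ratio 1.14, adjusted p = 0.00645). Over Sγ1 and Sε alone, with fewer junctions, the CtIP_AA odds ratios were 0.934 for microhomology (0.847 to 1.03) and 1.13 for insertions (1.01 to 1.26), neither past the threshold (exact adjusted p = 0.239 and 0.0535).

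By region, the XRCC4_KO change was smallest in Sε. Blunt joins went from 23.0% to 13.1% in Sγ1 (odds ratio 0.507, exact adjusted p = 1.06e-16), from 19.6% to 10.5% in Sμ (odds ratio 0.482, adjusted p = 2.35e-11) and from 25.2% to 20.6% in Sε (odds ratio 0.770, adjusted p = 0.0743). The joins in Sε did change in XRCC4_KO. Microhomology went there from 49.0% to 58.9% (odds ratio 1.49, exact adjusted p = 0.000299, against odds ratios of 2.24 in Sγ1 and 2.07 in Sμ). Insertions went from 25.8% to 20.6% (odds ratio 0.744, exact adjusted p = 0.0405, against 0.575 and 0.658). Blunt against microhomology joins alone had an odds ratio of 0.680 in Sε (exact adjusted p = 0.00601). The odds ratios of the 3 regions differed from each other by Woolf's test of homogeneity for blunt joins (chi-square 9.78, 2 degrees of freedom, adjusted p = 0.0225 over 9 such tests, chosen after the data were seen) and for microhomology (chi-square 11.7, adjusted p = 0.0128). Some reads may have been counted in a wrong library, as described below. Any from Wildtype would weigh most in Sε, which takes 13.1% of XRCC4_KO and 27.8% of Wildtype junctions. The region differences were not recomputed without such reads and cannot be told apart from this source.

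Long microhomology, of 4 or more bp among joins with 1 to 15 bp, was 17.8% in Wildtype (16.7 to 18.9), 19.3% in CtIP_AA (17.4 to 21.4), 18.9% in CtIP_KO (16.8 to 21.1) and 32.8% in XRCC4_KO (30.9 to 34.7). XRCC4_KO exceeded Wildtype with an odds ratio of 2.26 (2.01 to 2.53, exact adjusted p = 1.1e-42), and the CtIP libraries did not differ detectably from it (adjusted p = 0.351 and 0.562). In Sγ1 the share went from 15.1% to 33.3% in XRCC4_KO (odds ratio 2.80, exact adjusted p = 1.67e-30), in Sμ from 23.0% to 32.2% (odds ratio 1.59, adjusted p = 6.95e-05) and in Sε from 12.3% to 16.5% (odds ratio 1.42, adjusted p = 0.172). The Sμ difference was lost at a cut-off of 6 or more bp (odds ratio 1.16). That in Sε passed the test when taken over all Sε junctions (odds ratio 1.69, exact adjusted p = 0.0121). Taken so, it also rises with the share of Sε joins with any microhomology, 58.9% in XRCC4_KO and 49.0% in Wildtype. Among joins with microhomology it did not pass at 6 or more bp (odds ratio 1.33, exact adjusted p = 0.933) or 2 or more bp (odds ratio 1.09, adjusted p = 0.736). At 2 or more bp, a cut-off chosen after the data were seen, CtIP_AA exceeded Wildtype in Sε (odds ratio 1.37, 1.07 to 1.77, exact adjusted p = 0.0306), which it did not at 4 or more bp (odds ratio 1.13, adjusted p = 0.629) or 6 or more bp (odds ratio 1.01, adjusted p = 1). Where per-junction lengths were compared, the mean in Sε was 2.18 bp in CtIP_KO and 2.22 bp in XRCC4_KO (permutation adjusted p = 0.747), in Sγ1 2.35 bp in CtIP_AA and 2.45 bp in CtIP_KO (adjusted p = 0.591), and in Sμ 2.57 and 2.62 bp in the same libraries (adjusted p = 0.747).

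**Figure D2:**
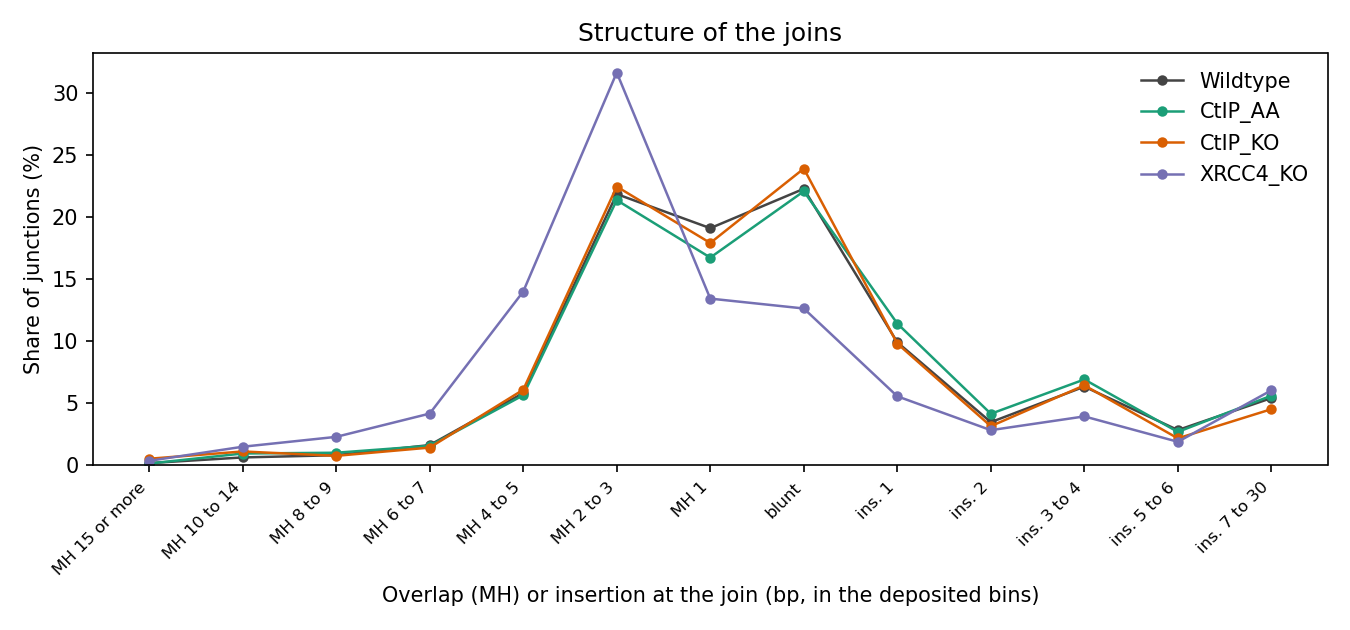
Share of junctions (%) by the length of overlap (MH, microhomology) or insertion at the join, in bp and in the deposited bins, which differ in width. Points are the 4 libraries, joined by lines for reading only, with no error bars. XRCC4_KO has 31.6% of joins with 2 to 3 bp of microhomology against 21.8% in Wildtype, and 12.6% against 22.2% blunt.

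Among joins with insertions, those of 2 or more bp were 64.5% in Wildtype, 62.9% in CtIP_AA, 62.3% in CtIP_KO and 72.5% in XRCC4_KO, where they were raised (odds ratio 1.45, 1.21 to 1.75, exact adjusted p = 0.000108). Large insertions of over 30 bp, which the deposited totals leave out, were 7.00% of all junctions in Wildtype, 12.2% in CtIP_AA (odds ratio 1.84, exact adjusted p = 2.56e-20) and 17.4% in CtIP_KO (odds ratio 2.80, adjusted p = 7.29e-59). Most of these reads had no recorded read length (74.6%, 69.6% and 73.9%) or had the bait primer itself as prey (17.6%, 25.8% and 22.9%). Over the remaining reads the odds ratio was 1.09 in CtIP_AA (0.614 to 1.85) and 1.16 in CtIP_KO (0.631 to 2.04, exact adjusted p = 0.869 for each). Reads without a read length had longer insertions (medians of 78, 80 and 79 bp against 41, 46 and 37 bp), so leaving them out can remove the longest insertions. Preys at the primer were identified only among reads with a read length. With those left out, reads with the prey in a switch region, with or without a read length, numbered 99, 41 and 42. Their odds ratio was 1.21 in CtIP_AA (0.820 to 1.77, exact adjusted p = 0.401) and 1.57 in CtIP_KO (1.06 to 2.28, adjusted p = 0.0465), a test chosen after the data were seen.

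Deletional junctions were 94.7% of Sε, 91.8% of Sγ1 and 77.1% of Sμ junctions in Wildtype. Over the 3 regions together the deletional share was 88.8% in Wildtype, 90.6% in CtIP_AA (odds ratio 1.21, exact adjusted p = 0.0239), 88.5% in CtIP_KO (adjusted p = 0.778) and 84.5% in XRCC4_KO (odds ratio 0.688, 0.612 to 0.775, adjusted p = 1.33e-08). XRCC4_KO has more Sμ and fewer Sε junctions, which lowers this share by itself. Stratified by region, a test chosen after the data were seen, its odds ratio was 0.809 (0.717 to 0.913, exact adjusted p = 0.0046). It was 0.937 in Sε alone (exact adjusted p = 0.819) and 0.837 in Sμ (adjusted p = 0.0841). In Sμ, CtIP_AA was higher at 83.1% (odds ratio 1.47, exact adjusted p = 0.00129), and in Sγ1, XRCC4_KO was lower at 89.3% (odds ratio 0.748, adjusted p = 0.0212). The CtIP_AA difference over the regions ended when Sμ was left out (odds ratio 1.10), and the Sγ1 difference in XRCC4_KO ended when each position was counted once (odds ratio 0.848). Counting positions once removes more junctions from the denser deletional side of the deeper Wildtype library, which can raise this odds ratio by itself. In Sε no library differed detectably from Wildtype.

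Positions are given on mm9 chromosome 12, where lower coordinates lie downstream. Deletional Sγ1 junctions had a median at 114573668 in Wildtype (bootstrap interval 114573613.5 to 114573717) and 282 bp higher in CtIP_AA (permutation adjusted p = 0.00015). The Sε median was 114513778 in Wildtype and 201 bp higher in CtIP_AA (permutation adjusted p = 0.00025), while the Sμ median, 114663386 in Wildtype, was lower by 47 bp in CtIP_AA (adjusted p = 0.025). With each position counted once the Sμ shift in CtIP_AA was 81 bp and did not pass the test (permutation adjusted p = 0.0783), and the mean was lower by 95.1 bp (adjusted p = 0.0206). No median of CtIP_KO differed from Wildtype (permutation adjusted p = 0.191 in Sε, 0.501 in Sγ1 and 0.825 in Sμ). XRCC4_KO had a lower Sμ median, by 46 bp (permutation adjusted p = 0.0242), and its medians in Sγ1 and Sε did not pass the test (adjusted p = 0.0669 and 0.203).

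The tail of the distribution moved more than the median in XRCC4_KO. Downstream of the Sμ core (114662305 to 114665763) lay 2.51% of Wildtype and 16.0% of XRCC4_KO deletional junctions (odds ratio 7.42, 5.19 to 10.8, exact adjusted p = 2.45e-33), and the 5th percentile sat at 114660442 in XRCC4_KO and 114662577.7 in Wildtype. Downstream of the Sγ1 core (114570384 to 114576297) lay 2.51% of Wildtype and 7.39% of XRCC4_KO junctions (odds ratio 3.10, exact adjusted p = 9.27e-14). In Sε (core 114511918 to 114515051) the shares were 2.49% and 3.21% (exact adjusted p = 0.854). CtIP_KO did not differ detectably from Wildtype in the 3 regions (exact adjusted p = 0.892 in Sγ1 and Sμ and 0.854 in Sε). For CtIP_AA the Sγ1 odds ratio of 0.570 (exact adjusted p = 0.0826) passed the test with each position counted once (0.487) and with the core border 1 kb further in (0.544). Counting positions once removes more junctions from the dense core of the deeper Wildtype library, which can lower this odds ratio by itself. The Sμ odds ratio of CtIP_AA, 0.903, turned to 1.38 with the border 1 kb further in (exact adjusted p = 0.00189). That border lies among the dense Sμ junctions and marks no tail. At or below 114663300 lay 39.3% of Wildtype and 47.7% of CtIP_AA junctions.

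**Figure D3:**
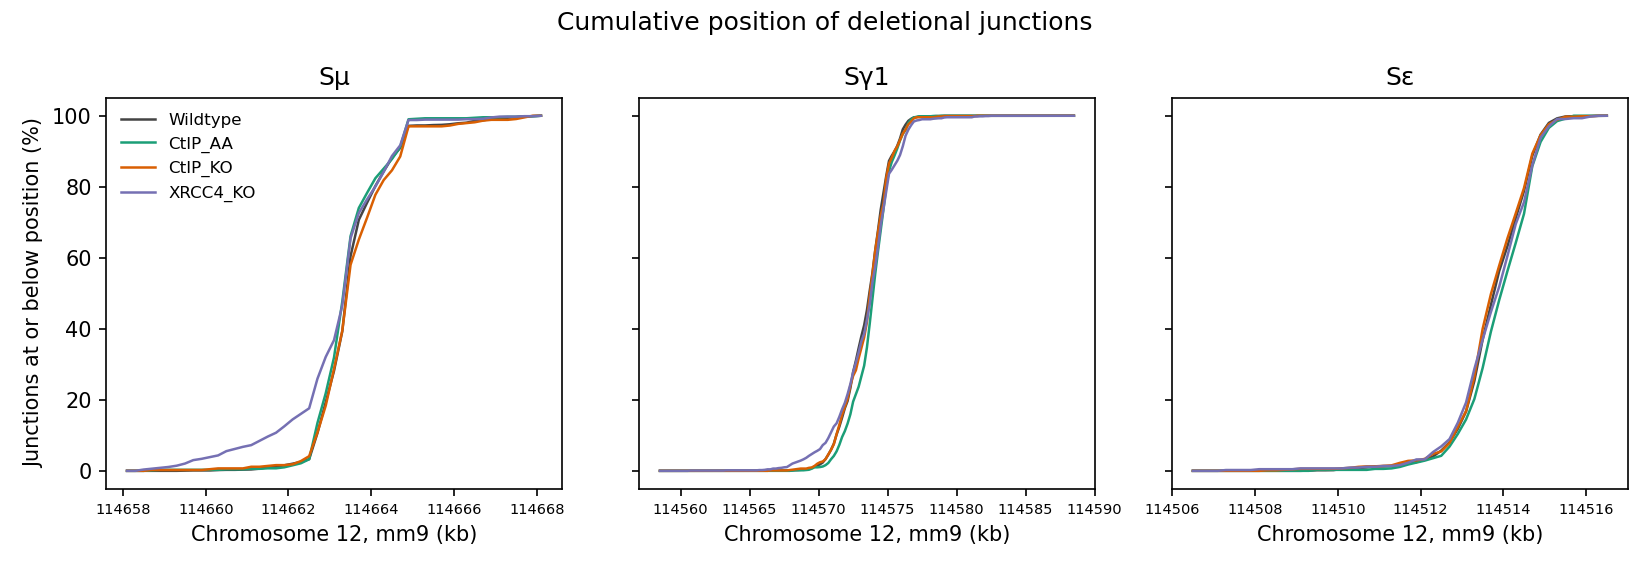
Cumulative share (%) of deletional junctions at or below each mm9 chromosome 12 position (kb), in steps of 200 bp, for Sμ, Sγ1 and Sε in the 4 libraries. Lower coordinates are downstream. In Sμ the XRCC4_KO curve rises earliest, with 16.0% of its junctions downstream of 114662305.

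On the bait side, blunt joins kept a median of 64 bp of bait in Wildtype, 65 bp in CtIP_AA, 62 bp in CtIP_KO and 61 bp in XRCC4_KO. Only XRCC4_KO differed from Wildtype (3 bp shorter, permutation adjusted p = 0.0298). The difference passed the test among Sγ1 preys alone (7.5 bp shorter, permutation adjusted p = 0.0004), but not among Sε preys (3.5 bp shorter, adjusted p = 0.36), among Sμ preys (0 bp, adjusted p = 1) or with each bait position counted once (6 bp shorter, adjusted p = 1). Counted once, bait positions show only which lengths occur, which depends on depth, so that alternative cannot weigh a small shift. Bait mismatches in Sε junctions were 2.07% of bases in Wildtype, 6.05% in CtIP_AA, 8.58% in CtIP_KO and 3.89% in XRCC4_KO, with odds ratios of 3.04, 4.43 and 1.91. The share of Sε reads with any mismatch was 12.8%, 13.7%, 12.5% and 12.1% in the same order, and did not differ from Wildtype in any library (exact adjusted p = 0.929). In the listed reads, 14 of CtIP_AA, 19 of CtIP_KO and 5 of XRCC4_KO, whose bait alignment did not end at the primer, held 92.5%, 95.9% and 90.8% of the mismatches.

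Outside IgH, junctions on chromosome 12 made up 22.8% of those of Wildtype (75 of 329), 11.7% of CtIP_KO (18 of 154, odds ratio 0.449, exact adjusted p = 0.00842) and 22.0% of XRCC4_KO (59 of 268, adjusted p = 0.844). The listed junctions fell in 223 bins of 1 Mb in Wildtype, 133 in CtIP_KO and 214 in XRCC4_KO, of which 12, 3 and 10 held 3 or more distinct junctions. The bin with the most was chromosome 7 from 132 to 133 Mb in each of these 3 libraries, with 13 of 305 distinct junctions in Wildtype (4.26%, 2.51 to 7.15), 6 of 151 in CtIP_KO (3.97%) and 10 of 262 in XRCC4_KO (3.82%). Chromosome 12 from 70 to 71 Mb held 10 in Wildtype, 1 in CtIP_KO and 6 in XRCC4_KO. The chromosome 12 bins from 114 to 117 Mb held 8, 9 and 6 in Wildtype, 1 each in CtIP_KO and 4, 7 and 4 in XRCC4_KO. Sμ, Sγ1 and Sε lie in the bin from 114 to 115 Mb, so these bins lie at or near IgH. Their junctions are part of the chromosome 12 shares above, which were not recomputed without them. In Wildtype the bin on chromosome 6 from 70 to 71 Mb held 7, that from 122 to 123 Mb held 5, and that from 129 to 130 Mb held 5. Chromosome 12 from 63 to 64 Mb held 6 and from 117 to 118 Mb held 5. CtIP_KO held 1 in each of these bins, and XRCC4_KO held 2, 3, 0, 3 and 0 in the same order. CtIP_KO had 4 on chromosome 2 from 98 to 99 Mb and 3 on chromosome 12 from 3 to 4 Mb. Each of these bins held 2 in Wildtype and 1 in XRCC4_KO. XRCC4_KO had 3 on chromosome 1 from 36 to 37 Mb, where Wildtype had 2 and CtIP_KO had 1. It also had 3 each on chromosome 5 from 114 to 115 Mb and chromosome 6 from 114 to 115 Mb, where Wildtype and CtIP_KO had 0. At these counts no single bin was tested between libraries. Mean microhomology at joins outside IgH was 5.10 bp in Wildtype, 4.50 bp in CtIP_KO and 5.44 bp in XRCC4_KO, with no detectable difference from Wildtype (permutation adjusted p = 0.591 for both).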

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

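All the tests in this part were chosen after the results they bear on were seen. Large insertions, which the main totals leave out, were 12.2% of junctions in CtIP_AA and 17.4% in CtIP_KO, above the 7.00% of Wildtype. Reads with the bait primer as prey (primer reads) were identified only among reads with a read length. Apart from these, 12.6% of large insertions in CtIP_AA (9.44 to 16.7) had the prey in a switch region. The share was 10.3% in CtIP_KO (7.73 to 13.7) and 17.4% in Wildtype (14.5 to 20.7). It was 94.3%, 92.8% and 95.3% of the junctions in the same order. Among large insertions with a read length, 19 of 20, 17 of 17 and 51 of 54 had such a prey. The low share thus comes from reads without one (22 of 305, 25 of 390 and 48 of 516) and does not exclude joins placed like other joins. Primer reads numbered 122, 113 and 121 in Wildtype, CtIP_AA and CtIP_KO, as a fixed background diluted by fewer junctions would (chi-square p = 0.815), but reads without a read length, which are most of the excess, numbered 516, 305 and 390 and argue against it for that part (chi-square p = 7.49e-13). Among reads with the prey in a switch region the odds ratio against Wildtype was 1.57 in CtIP_KO (1.06 to 2.28) and 1.21 in CtIP_AA (0.820 to 1.77). Of these reads, 25 of 42 in CtIP_KO and 48 of 99 in Wildtype lacked a read length, and primer preys were not left out among them. The CtIP_KO value goes with more large insertions at joins from the loss of CtIP, but cannot tell them from such reads. The CtIP_AA value leaves the substitution open. Whether the other reads are junctions stays open: without primer reads and reads lacking a read length the odds ratios were 1.09 (0.614 to 1.85) and 1.16 (0.631 to 2.04) in CtIP_AA and CtIP_KO, but the reads left out had longer insertions (median 79 bp against 37 bp in CtIP_KO), and their prey ends, with a median of 26 bp, may be misplaced.

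The bait mismatch rate was 3.04 times the Wildtype odds in CtIP_AA and 4.43 times in CtIP_KO. Reads whose bait alignment did not end at the primer held 92.5% of mismatches in CtIP_AA and 95.9% in CtIP_KO, so a few such alignments may be the source. More mutation of bait DNA across junctions would raise the share of reads with a mismatch, and its odds ratio was 1.08 in CtIP_AA (0.847 to 1.37) and 0.969 in CtIP_KO (0.751 to 1.24). The table of listed reads was not used here for Wildtype, so its mismatches were not split the same way.

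Some blunt junctions had the same prey position, strand and bait end in 2 libraries, and 109 of 439 blunt reads of XRCC4_KO and 626 of 2090 of Wildtype carried 6 bases before the nested primer. Of 22 such pairs of reads in Wildtype and XRCC4_KO, 15 had the same leader, against a mean of 1.68 and a highest value of 9 with leaders shuffled (permutation p = 0.0001, the smallest that 10000 shuffles can give, adjusted p = 0.0003 over 6 pairs of libraries), as had 7 of 15 in Wildtype and CtIP_KO (adjusted p = 0.0003), 2 of 6 in CtIP_AA and CtIP_KO (adjusted p = 0.0004), 2 of 2 in CtIP_AA and XRCC4_KO (adjusted p = 0.0021) and 2 of 4 in CtIP_KO and XRCC4_KO (adjusted p = 0.00216), but 1 of 13 in Wildtype and CtIP_AA (adjusted p = 0.126). That argues against the same join formed separately in Wildtype and XRCC4_KO, and is in line with reads of one library counted in another, a source that could reach CtIP_AA and CtIP_KO as well. Among blunt reads without a leader, the Sε share over Sε plus Sγ1 had an odds ratio of 0.606 for XRCC4_KO against Wildtype (0.636 over all blunt reads), so the difference did not rest on them. Which library such reads came from was not settled, and joins other than blunt ones were not examined. The smaller changes of XRCC4_KO in Sε, in structure and microhomology length, were not recomputed without such reads.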

How the results depend on the processing

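The values of this part are odds ratios against Wildtype unless said otherwise. Of 454 recomputed values, 356 kept their direction and their side of the threshold, 42 lost significance, 12 gained it and 44 changed direction, and the cause of these changes was not tested unless stated. In XRCC4_KO, the share of junctions landing in Sε (also over Sε plus Sγ1), the blunt, microhomology and insertion shares over all junctions, long microhomology over all junctions and the downstream tails of Sμ and Sγ1 kept their calls under each alternative run. Alternatives with a cut-off of 2, 5 or 7 bp, over blunt reads or those without a leader, leaving microhomology over 15 bp out of the structure shares, without primer reads or reads lacking a read length, with preys in a switch region, stratified by region, by reads with a mismatch, or counting positions once for the Sε over Sε plus Sγ1 share were chosen after seeing the data. A cut-off of 3 or more bp for microhomology and of 6 or more bp for insertions was not run, since the deposited bins do not separate these lengths, and 1 bp against more is the same split as 2 or more. The deposited mismatch counts hold no insertions or deletions. No paired analysis was possible because each group is 1 library, and for the same reason none could be left out. Depth limits the rarer classes most: an odds ratio of 1.09 in CtIP_AA large insertions rests on 20 reads.

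Counting each prey position once, which removes more junctions from deeper libraries, gave 0.879 for Sμ in CtIP_KO, 1.05 for Sγ1 in XRCC4_KO, 0.892 for Sε in CtIP_AA, and 0.906 and 1.11 for the Sε over Sε plus Sγ1 share in CtIP_AA and CtIP_KO. Leaving Sμ out gave 1.12 and 0.841 for Sγ1 in CtIP_AA and CtIP_KO, and leaving out junctions outside IgH gave 1.15 for Sε in CtIP_KO, all 3 now past the threshold. In blunt reads the Sε share of CtIP_AA was 0.856, and 0.859 without a leader.

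For structure, blunt against microhomology alone gave 1.05 for CtIP_AA blunt joins (1.05 in Sε), 0.956 for its microhomology (1.01 in Sγ1), 0.937 for CtIP_KO microhomology and 0.680, now past the threshold, for XRCC4_KO blunt joins in Sε, with 1.02 for CtIP_AA against CtIP_KO microhomology (1.05 in Sγ1). Counting large insertions turned the CtIP_KO directions, with 0.941 for blunt joins and 0.817 and 1.30 for microhomology and insertions, which both passed the test, and 1.00 for CtIP_AA against CtIP_KO microhomology. Sγ1 and Sε alone gave 0.934 and 1.13 for CtIP_AA microhomology and insertions and 0.939 for CtIP_KO microhomology. Large insertions without primer reads or reads lacking a read length were 1.09 and 1.16 in CtIP_AA and CtIP_KO, and those with the prey in a switch region 1.21 in CtIP_AA and 1.57, still past the threshold, in CtIP_KO.

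For long microhomology, 6 or more bp gave 0.736 in Sε and 1.17 in Sμ for CtIP_KO, 1.16 in Sμ for XRCC4_KO, 1.11 in Sγ1 and 0.791 in Sμ for CtIP_AA against CtIP_KO and 1.01 in Sμ for CtIP_KO against XRCC4_KO. At 2 or more bp it was 1.37 in Sε, now past the threshold, 0.983 in Sγ1 and 1.01 in Sμ for CtIP_AA, and 1.17 in Sε for CtIP_KO against XRCC4_KO. Over all junctions, where the share also rises with that of joins with any microhomology, it was 1.69 in Sε for XRCC4_KO, now past the threshold (1.33 at 6 or more and 1.09 at 2 or more bp were not), and 0.966 for CtIP_AA against CtIP_KO, and with microhomology over 15 bp 0.995 for the latter. The mean length in Sε then differed by 0.0372 bp between CtIP_KO and XRCC4_KO.

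For orientation, each position once gave 1.23, 1.05 and 1.29 in Sε for CtIP_AA, CtIP_KO and XRCC4_KO, 1.16 and 0.848 in Sγ1 for CtIP_KO and XRCC4_KO, and 1.22 for CtIP_KO over the regions, where leaving out Sμ gave 1.10 for CtIP_AA. Orientation odds ratios against the deeper Wildtype library can rise by depth alone when positions are counted once. For position, each position once put the Sμ median at -81 bp in CtIP_AA, a larger shift that lost the call, and at -43 bp in CtIP_KO, and the mean in Sγ1 differed by 48.1 bp between CtIP_KO and XRCC4_KO. Downstream of the core, each position once gave 0.892 and 0.859 in Sε for CtIP_KO and XRCC4_KO, 0.487 (now past the threshold) and 0.855 in Sγ1 for CtIP_AA and CtIP_KO, 0.790 in Sμ for CtIP_KO and 1.04 in Sε for CtIP_KO against XRCC4_KO. Counting positions once thins the dense core of the deeper Wildtype library most, which can lower the odds ratios against Wildtype by itself. A border 1 kb further out gave 0.919 in Sε for XRCC4_KO and 1.10 for CtIP_KO against XRCC4_KO, and 1 kb further in gave 0.544 in Sγ1 and 1.38 in Sμ for CtIP_AA and 1.39 in Sμ for CtIP_AA against CtIP_KO, all 3 past the threshold, and 0.988 in Sμ for CtIP_KO. The Sμ border 1 kb further in lies among the dense junctions and marks no tail.

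The median bait length differed by -2.5 bp in CtIP_AA and -6 bp in XRCC4_KO with each bait position once, and by -3.5 bp among Sε preys and 0 among Sμ preys in XRCC4_KO, where all 3 lost the call, and by -3 bp among Sμ preys between CtIP_KO and XRCC4_KO. With each bait position once, only the lengths that occur are compared, whatever their number of reads. Bait mismatches at C and G gave 1.02 in XRCC4_KO, and reads with a mismatch 1.08, 0.969 and 0.940 in CtIP_AA, CtIP_KO and XRCC4_KO and 1.12 for CtIP_AA against CtIP_KO.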

Other observations

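The tests in this part were chosen after the data were seen. Joins outside IgH differed in structure from joins to the switch regions of the same library. In Wildtype, 51.2% of microhomology joins outside IgH (103 of 201, 44.4 to 58.1) had 4 or more bp, against 16.2% in the 3 switch regions together (odds ratio 5.43, 4.03 to 7.33, Fisher's exact adjusted p = 7.23e-28 over 6 tests). The shares were 41.0% and 16.6% in CtIP_KO (odds ratio 3.49, exact adjusted p = 4.59e-08) and 55.8% and 30.7% in XRCC4_KO (odds ratio 2.84, adjusted p = 1.35e-11). Blunt joins were fewer outside IgH, at 11.6% against 22.7% in Wildtype, 14.3% against 24.5% in CtIP_KO and 5.60% against 13.3% in XRCC4_KO.

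Joins within Sμ carried insertions more often than joins to Sγ1 and Sε in each of the 4 libraries, at 34.1% against 25.9% in Wildtype (odds ratio 1.49, 1.34 to 1.65), 37.5% against 28.3% in CtIP_AA, 32.7% against 25.2% in CtIP_KO and 25.4% against 17.6% in XRCC4_KO (exact adjusted p at most 0.000599 over 4 tests). The most used deletional Sε position of Wildtype, chromosome 12 at 114514526, held 25 of 2487 junctions there, 11 of 732 in CtIP_AA, 3 of 713 in CtIP_KO and 4 of 436 in XRCC4_KO.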
